A study of Mus musculus with 2 samples.

How the data were processed

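Drop-seq libraries of mouse aortic and mitral heart valve cells were made at postnatal days 7 and 30, 1 library per age, per the labels' protocols. The number of animals behind each library was not given. The deposited tables give UMI counts per gene and cell barcode as the authors made them, whole numbers with no normalization. The genome build mm10 and the aligner Bowtie2 2.2.7 are named per the submitters' processing notes, with no role stated, and the counting program and gene annotation are not given in the sources used here. The deposited normalized tables hold UMI counts per 10000 UMIs of each barcode on a linear scale, by the authors. This was checked on all 19475626 values of the P7 and 77355312 of the P30 library, which equalled the count tables so scaled within 1e-06. Both deposited tables hold the same barcodes, and the lowest number of detected genes per barcode was 500 in both libraries, so a minimum was applied before deposit without being stated. Cell types were named here from markers, as no annotation of the cells was used.

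The P7 library held 20266 genes with a UMI and the P30 library 22026, with 18590 in both. UMIs per barcode ran from 622 to 33151 at P7 and from 637 to 172266 at P30. Barcodes over 20000 UMIs numbered 7 and 20 and held 5.98% and 9.24% of UMIs. Barcodes whose last base was N numbered 260 and 314, and 11 and 38 pairs of barcodes differed by 1 base. Cells were kept with at least 300 detected genes and at most 20% mitochondrial UMIs, which removed 0 and 0 barcodes for genes and 2 and 17 for mitochondrial UMIs. Doublets were called by Scrublet in scanpy 1.11.5 within each library and removed, 3 and 1 barcodes. This left 4450 of 4473 barcodes.

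Cells of both libraries were clustered together. Counts were scaled to 10000 UMIs per cell and log transformed, 2000 variable genes were ranked within each library, and 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.8 on a graph weighted by shared neighbours gave 15 clusters. Each cluster was matched to 1 of 14 marker sets, the set with the highest mean log2 level over its level in the other clusters (10 CPM added), and a name required at least 3 markers at 50 CPM or more. A cluster stayed outside the classes where its top 10 genes by fold held more markers of another class, or markers of 3 or more classes. After the clusters were seen, the rule was extended, and a name also needed 50% of its markers detected and 50% of the cells carrying 2 of them. Cluster 1 was kept apart because the mural markers Rgs5 and Tagln were in its top 10 genes and no interstitial marker was. Cluster 9 was kept apart because 19.4% of its cells carried 2 mast cell markers. Interstitial-like cells were mostly of clusters 3 (385 cells), 5 (286) and 11 (36) at P7 and of clusters 0 (1354), 2 (479), 8 (73) and 11 (26) at P30. Endothelial-like cells were of clusters 4 (81 and 212) and 7 (42 and 81), and macrophage-like cells of clusters 6 (49 and 205) and 13 (2 and 35).

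Classes with at least 30 cells in both libraries were compared between the ages, with counts summed over the cells of a class and given per 1000000 (CPM). A gene was measured in a class with at least 20 CPM and 10 counts in the higher library. Levels carry exact Poisson intervals, ratios exact binomial intervals conditional on the summed count, and shares exact Clopper-Pearson intervals, all at 95%. A gene without a count in 1 library was set at a floor of 3 counts there, and its ratio is a bound. This floor was carried into list medians and alternatives after a first run of the alternatives. With 1 library per age no test was made and no p-value is given. For each of 32 gene lists the median log2 ratio was taken over measured members, where at least 3 were measured, with the order-statistic interval over members, and its percentile among 10000 random lists drawn from the 100 genes nearest in mean expression describes these libraries only. A list member is called higher or lower when its ratio was at least 2-fold and its interval excluded equal levels. Genes named singly were the 12 per direction (8 in macrophage-like cells) at least 2-fold apart whose interval bound nearest to equal levels lay farthest from it. Mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out, as were genes whose class level in the higher library was under 50% of the level over all kept cells. Other genes appear as members of the lists or, for mt-Rnr2, Malat1 and those of the sub-clusters, were chosen after their values were seen.

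Shares of cells with a UMI are given as the share expected when each cell is thinned to 500 UMIs, averaged over all possible thinnings, and unthinned. No cell had fewer than 500 UMIs. The average replaced a single random thinning after the data were seen, because single draws differed widely in the 51 P7 macrophage-like cells. Sub-clusters were made within a class and library from 15 principal components at resolution 0.8, without genes of the lists or markers. List levels in a sub-cluster were then compared with the other cells of that class and library, as sums of CPM with exact intervals. Gene positions are from GENCODE M21 on mm10 and were found for 622 of 633 symbols looked up. The files name genes by symbol alone. Genes with near-identical copies, such as the Hist1h2a, C4, Bglap, Mir692 and Ccl21 genes and the MHC class I genes, cannot be separated with certainty in 3' counts of unstated read assignment.

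The gene lists, markers, comparisons, rule for named genes and most alternatives were fixed before the data were examined. Alternatives were doublets kept, each library clustered alone, resolution 1.5, median-of-ratios scaling, totals without mitochondrial, ribosomal protein and haemoglobin genes, the mean over cells of each cell's CPM, thinning to 500 UMIs, no expression minimum and the authors' normalized table. A further 4, chosen after the data were seen, were at least 800 genes per cell, leaving out barcodes over 20000 UMIs and barcodes 1 base away from a barcode at least 20 times deeper, counting cluster 1 as interstitial, and leaving out clusters led by cell cycle genes.

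The comparison was tested on simulated counts with known ratios. These were drawn from 1 pooled profile per class with no spread between cells. They do not test genes whose counts lie in a few barcodes, such as Fabp4 in endothelial-like cells. For interstitial-like cells (6321 genes) the intervals held the true ratio for 95.7% of genes, 100% of 4-fold differences in either direction were found, and 0 of 6126 equal genes passed 2-fold. For endothelial-like cells (7065 genes) these were 95.9%, 100% of 4-fold higher and 97.7% of 4-fold lower genes, and 84 of 6877. For macrophage-like cells (4230 genes) they were 96.5%, 96% and 100%, and 71 of 4089. Genes exactly 2-fold apart were found in 36% (higher) and 50% (lower), 54% and 46.7%, and 32% and 52% of cases in these classes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.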

Results

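Single cells of mouse aortic and mitral heart valves (strain C57BL/6J) were profiled by Drop-seq, a droplet assay that counts 3' ends of transcripts by unique molecular identifier (UMI), at postnatal day 7 (P7) and postnatal day 30 (P30). Each age was represented by 1 library, so no difference between the ages had a replicate check, and values below compare those libraries. The P7 library held 961 barcodes and 3116184 UMIs, with a median of 2215 UMIs and 1227 genes per barcode. The P30 library held 3512 barcodes and 11267724 UMIs, with a median of 2440.5 UMIs and 1209 genes per barcode. Filters on detected genes, mitochondrial UMIs and called doublets kept 956 P7 and 3494 P30 cells. The doublet caller marked 3 barcodes in the P7 library and 1 in the P30 library, too few to count as having worked, so doublets remain. The libraries carried different run names, so age and sequencing run could not be told apart. Mitochondrial mt-Rnr2 took 0.420% of UMIs in the P7 library and 2.83% in the P30 library, and the nuclear noncoding RNA Malat1 took 1.06% and 3.94%. Intervals of levels, ratios and shares are 95% and cover counting error only. Those of list medians are order-statistic intervals over the members, the full range in the shortest lists, and show the spread between genes.

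Interstitial-like cells, the fibroblast-like cells that lay down valve matrix, were the largest class in both libraries. They made up 74.7% (71.8 to 77.4, exact binomial interval) of P7 cells and 55.7% (54.0 to 57.3) of P30 cells. Endothelial-like cells, which line the leaflet surface, made up 12.9% (10.8 to 15.2) and 8.39% (7.49 to 9.35). Macrophage-like cells made up 5.33% (4.0 to 6.95) and 6.87% (6.05 to 7.76), but 0% of P7 cells with each library clustered alone, where no macrophage comparison could be made. Dendritic-like cells made up 0.628% (0.231 to 1.36) and 1.63% (1.24 to 2.11). Melanocyte-like cells made up 1.46% (0.803 to 2.44) of P7 and 0.458% (0.262 to 0.743) of P30 cells. Erythroid-like cells made up 1.57% (0.881 to 2.57) and 1.03% (0.723 to 1.42). They also carried interstitial markers, with Dcn at 10446 CPM and Col1a2 at 6781, so interstitial cells or multiplets with haemoglobin RNA may be among them. Clusters 1 and 9 were kept out of every class and together held 3.45% of P7 and 26.0% of P30 cells. Cluster 1 held 873 P30 cells and no P7 cell, and carried all 10 interstitial markers while the mural genes Rgs5 and Tagln were among its leading genes. With cluster 1 counted as interstitial, that class was 80.7% of the P30 library. Class shares can also reflect dissociation and droplet capture.

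**Figure D1:**
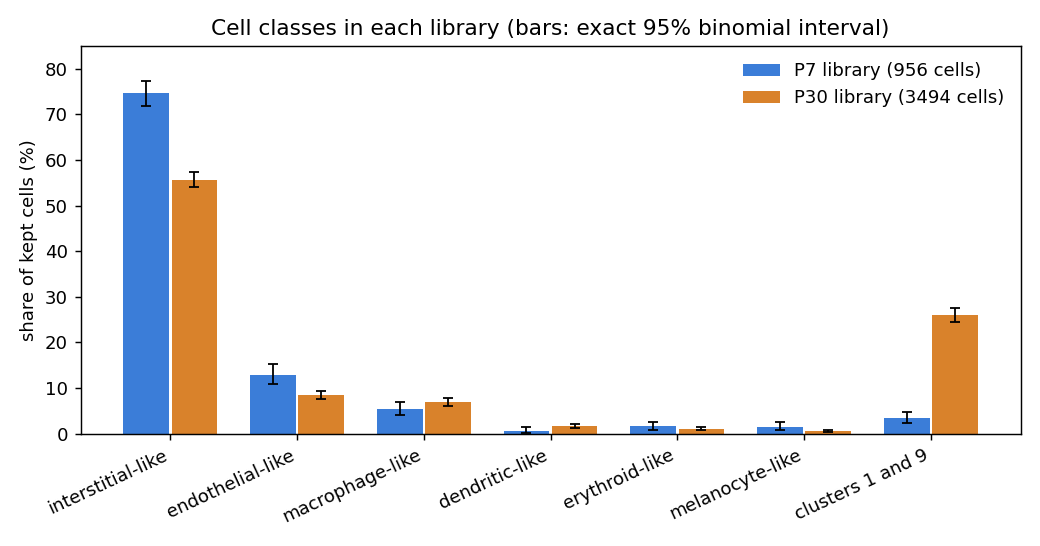
Share of kept cells (percent) in each cell class for the P7 and P30 libraries, with exact 95% binomial intervals as error bars. Interstitial-like cells were 74.7% of P7 and 55.7% of P30 cells, and the clusters kept apart were 3.45% and 26.0%.

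The question put to the interstitial-like cells was how their transcripts differed between the ages. Complement, interferon response and major histocompatibility complex (MHC) class I genes stood higher in the P30 library, and fibrillar collagen, imprinted growth and cell cycle genes stood lower. Ifi27l2a, an interferon-inducible gene, was at 720 UMIs per 1000000 of the class (CPM; Poisson interval 698 to 743) in the P30 library against 4.09 (1.87 to 7.76) in the P7 library. Mmp3, which encodes the matrix protease stromelysin, was at 566 CPM (547 to 586) against 9.99 (6.26 to 15.1). C3, the central complement component, was at 37.3 CPM (32.5 to 42.7) in the P30 library with no count in the P7 library, at least 4.78 higher on the log2 scale against a floor of 3 counts. Postn, which encodes the matricellular protein periostin, was at 5335 CPM (5239 to 5433) in the P7 library and 1018 (992 to 1044) in the P30 library. The values come from 714 P7 cells with 2202797 UMIs, mostly of clusters 3, 5 and 11, and 1945 P30 cells with 5703191 UMIs, mostly of clusters 0, 2 and 8. The median log2 ratio of P30 over P7 across all measured genes was −0.30 in these cells, −0.20 in endothelial-like cells and 0.23 in macrophage-like cells, and gene group values are to be read against these.

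Matrix genes parted by type in the interstitial-like cells. From here on, CPM pairs give the P7 library first, and single values without a unit are log2 ratios of P30 over P7. Of 8 measured fibrillar collagen genes, 6 were at least 2-fold lower in the P30 library, with a median log2 ratio of −1.33 (−1.92 to 0.88) that lay at percentile 0 of 10000 random lists matched on expression. Col1a1 was at 6834 CPM against 2747, Col3a1 was at −1.49 and Col11a1 at −1.92 on the log2 scale, while Col5a3 was at 0.88. Of 14 other collagen genes 8 were at least 2-fold lower, with Col18a1 at −3.61, and Col8a2 was higher at 1.43. Elastic fibre genes had 6 of 16 members lower, among them elastin (Eln, 138 CPM against 11.2) and Fbn2 (492 against 37.3), and 3 higher, Mfap5 at 2.48, Efemp1 at 1.95 and Fbln1 at 1.22. Proteoglycan genes went both ways, with 6 of 22 higher and 5 lower, and their median of −0.13 had the other sign under median-of-ratios scaling. Prg4, which encodes the lubricant lubricin, was at 2842 CPM against 7593, and decorin (Dcn) at 8097 against 18377. Versican (Vcan) was lower at −1.25 and aggrecan (Acan) at −2.07. Collagen processing genes had 6 of 21 members lower, led by the crosslinking enzyme Lox at −2.76, and Pcolce2 was higher at 1.69. Among 17 matricellular genes 4 were lower, Postn at −2.39, Tnc at −2.31, Cthrc1 at −2.63 and Wisp1 at −2.29, and Comp at 1.96, Spp1 at 2.24 and Smoc1 at 1.32 were higher. Of 15 matrix protease and inhibitor genes 3 were higher (Mmp3, Htra3 and Timp3) and Htra1 and Mmp14 were lower, with a median of −0.26 that also had the other sign under median-of-ratios scaling.

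Genes of cartilage, tendon and bone had 8 of 15 members at least 2-fold higher in the P30 library and 3 lower, with a median log2 ratio of 1.96 (−0.65 to 2.24). Chad, which encodes the cartilage protein chondroadherin, was at 49.9 CPM (41.0 to 60.2) against 204 (192 to 216), and Comp, the cartilage oligomeric matrix protein gene, at 166 (150 to 184) against 646 (625 to 667). Cilp was higher at 3.68, the osteocalcin gene Bglap at 4.54, Cytl1 at 3.31 and the calcification inhibitor Mgp at 2.23. Col9a1 at −3.02, Matn4 at −2.41 and Acan were lower. Sox9 and Scx, which encode transcription factors of cartilage and tendon, were at −0.02 and 0.39. Thinned to 500 UMIs per cell, 5.68% (4.15 to 7.71) of P7 and 20.9% (19.1 to 22.8) of P30 interstitial-like cells had a Comp UMI, and without thinning 14.3% and 44.6%. In endothelial-like cells the thinned shares for Comp were 0.184% and 1.69%. Median depths were 2281.5 and 2547 UMIs in interstitial-like and 2277 and 2157 in endothelial-like cells.

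All 9 measured complement genes were at least 2-fold higher in the P30 library (median log2 ratio 2.36, 1.92 to 3.26), including C4b at 3.26, C1ra at 2.51 and the inhibitor gene Serping1 at 1.92. C4b and C4a are near-identical copies, so which copy was read is uncertain. MHC class I genes had 9 of 11 members higher (median 2.2, 0.73 to 3.52), with H2-K1 at 13.6 CPM (9.19 to 19.4) against 233 (221 to 246) and B2m at 525 against 2420. Interferon response genes had 15 of 20 members higher (median 1.98, 1.09 to 3.82), among them Isg15 at 5.22, Bst2 at 4.26 and, with 1 P7 UMI each, Ifit1 at 6.29 (3.80 to 11.6) and Rtp4 at 5.94 (3.44 to 11.3), and Ifitm1 was lower at −1.87. With each cell thinned to 500 UMIs Ifit1 and Rtp4 had no P7 count and were at least 1.72 and 1.43 higher against a floor of 3 counts. Chemokine genes had 6 of 9 members higher (median 1.24, 0.81 to 1.96), led by Cxcl1 at 2.24. The medians of these 4 lists lay at percentile 100 of the random lists. The ribosomal RNA mt-Rnr2, which has no immune function, was also higher in this class, at 2.54, and Malat1 at 1.88. Mitochondrial coding transcripts went the other way, at 2.75% of UMIs in P7 and 1.55% in P30 interstitial-like cells, 2.47% and 1.32% in endothelial-like cells, and 1.75% and 1.30% in macrophage-like cells.

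Imprinted growth genes had 8 of 13 members at least 2-fold lower in the P30 library and none higher (median −1.2, −3.53 to −0.04). Dlk1, which encodes a Notch-like protein that restrains fat cell formation, was at 27.7 CPM (21.2 to 35.6) against 1.05 (0.386 to 2.29), and H19 was at −4.0, Igf2 at −2.58 and Mest at −2.69. Cell cycle genes had 11 of 21 members lower and none higher (median −1.10, −1.32 to −0.63), with Mki67 at −1.41 and the replication helicase genes Mcm3 at −1.85 and Mcm6 at −1.65, while Top2a was at −0.30 and Pcna at −0.06. Thinned to 500 UMIs, 11.2% (8.99 to 13.8) of P7 and 3.70% (2.91 to 4.64) of P30 cells held at least 2 cell cycle UMIs, and without thinning 42.9% and 30.8%. With at least 800 genes required per cell those thinned shares were 7.65% and 2.36%, and the list median was −1.68. Notch genes had 4 of 8 members lower, Hey1 at −2.50, Notch3 at −2.03, Notch1 at −1.29 and Heyl at −1.10. Contractile genes had Myl9 at −1.47 and Flna at −1.05 lower, Lmod1 at 1.08 higher and Acta2 at −0.27 (median −0.65). Tagln, a member of this list, was among the genes that set cluster 1 apart. The P30 values thus leave out 873 cells with Tagln at 353 CPM, against 176 and 95.4 in clusters 0 and 2. Acta2 was at 151 CPM in cluster 1, against 150 and 55.2.

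The transforming growth factor beta and bone morphogenetic protein (BMP) list had a median of 0.08, with Tgfb2 lower at −1.89, Bmpr2 lower at −1.57 and Bmp2 higher at 1.01 among 17 members. Wnt genes had a median of −0.31, with the secreted Wnt binders Sfrp2 (2446 CPM against 349) and Sfrp1 lower and Wif1 and Frzb higher. Transcription factors of valve mesenchyme had 1 of 14 members lower, Snai2, and none higher. Immediate early genes, which dissociation can induce, had Jund and Hspb1 higher and none lower of 21 (median 0.42). The 19 nuclear genes of oxidative phosphorylation had none called higher or lower (median 0.29). Lipid handling genes had Apod, Lpl and Cebpb higher and Angptl4 lower of 7. Vascular adhesion genes went both ways, with Procr higher and Sele, Selp and Mcam lower of 9. All 4 haemoglobin genes, the marker of blood carried along, were lower in the P30 library (median −2.95).

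Genes named by the rule fixed beforehand as highest in the P30 interstitial-like cells, beside Ifi27l2a, Mmp3, C3, Isg15, Ifit1, H2-K1 and Rtp4, were Apod (1.36 CPM against 102), the cytochrome Cyp2e1 (2.72 against 105), the cytokine receptor chain Csf2rb at 6.35 (3.85 to 11.7, with 1 P7 UMI), Bglap2 at 5.17, a near-identical copy of Bglap, and the small nucleolar RNA Snord13 at 5.77. With each cell thinned to 500 UMIs Bglap2 was at 3.01 (1.08 to 6.10, with 2 P7 counts), and Csf2rb had no P7 count and was at least 1.22 higher. Those highest in the P7 library were Parm1 (32.2 CPM, 25.2 to 40.7, against 0.526, 0.108 to 1.54), Clca1 (148, 132 to 165, against 6.84, 4.86 to 9.35), the RNA-binding gene Igf2bp3 (25.4 against 0.877), Dlk1 and 8 Hist1h2a histone genes, from −3.99 for Hist1h2ag to −4.63 for Hist1h2ak. The histone genes are near-identical copies, so which copy was read is uncertain. Parm1 was at −5.94 and Dlk1 at −4.72, and with each cell thinned to 500 UMIs at −3.25 (−6.56 to −0.86) and −2.45 (−4.63 to −0.55). Without the clusters led by cell cycle genes Hist1h2ag was at −2.56 and Hist1h2ak at −3.43. In the mm10 genome build with GENCODE M21 gene models, Ifi27l2a lies on chromosome 12 from 103442167 to 103443680, Mmp3 on chromosome 9 from 7445822 to 7455975, C3 on chromosome 17 from 57203970 to 57228136 and Dlk1 on chromosome 12 from 109452823 to 109463336.

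**Figure D2:**
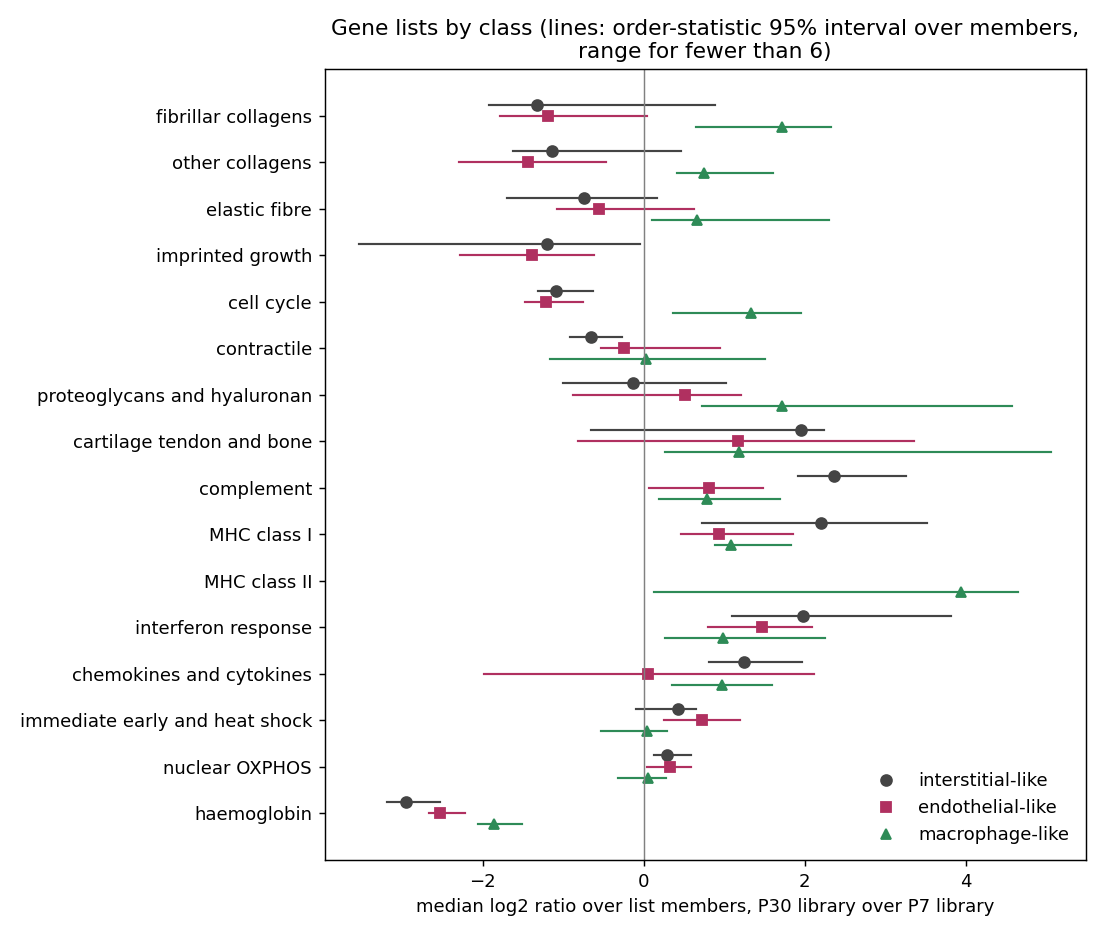
Median log2 ratio of P30 over P7 for selected gene lists in interstitial-like, endothelial-like and macrophage-like cells, 1 library per age. Lines show the 95% order-statistic interval over list members, or the full range in the shortest lists. Interferon response and MHC class I medians lay above 0 in all 3 classes, and the cell cycle median was −1.10, −1.22 and 1.33.

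Within each library, interstitial-like cells were split again with all listed genes and markers left out, and the listed genes were then read in the sub-clusters. At P7, sub-cluster 0 (142 cells) held cartilage, tendon and bone genes at 2.48-fold (2.39 to 2.57) the level of the other cells, with 11 of 12 members above, and Comp at 416 CPM, Chad at 134 and Fmod at 2222. At P30, sub-cluster 3 (271 cells) held them at 1.35-fold (1.33 to 1.37) with 11 of 14 members above, and sub-cluster 0 at 1.52-fold (1.5 to 1.54) with 8 of 14. Sub-cluster 3 had Chad at 780 CPM, Comp at 1843, Cilp at 761 and Fmod at 2576 CPM, and fibrillar collagens at 1.92-fold (1.90 to 1.95). Sums of the cartilage, tendon and bone list were weighted mostly by Mgp, at 3976 CPM in P7 and 18692 in P30 interstitial-like cells. All measured members of that list summed to 5585 and 21222 CPM. P7 sub-cluster 3 (99 cells) had fibrillar collagens at 2.87-fold (2.82 to 2.91), with Col1a1 at 20429 CPM, and the cartilage genes Matn4 at 888 CPM and Col9a1 at 600.2.

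Immune and lipid genes gathered in another sub-cluster of each library. At P30, sub-cluster 2 (396 cells) held chemokine genes at 5.73-fold (5.47 to 6.01), lipid handling genes at 2.41-fold, complement at 1.63-fold (1.57 to 1.68), MHC class I at 1.93-fold with 11 of 11 members above, and interferon response at 1.49-fold with 15 of 19. In it C3 was at 139 CPM, C4b at 683, Mmp3 at 2191 and Cxcl1 at 2442, while Ifi27l2a was at 604 CPM against 753 in the other cells. At P7, sub-cluster 4 (98 cells) held lipid handling genes at 3.66-fold (3.49 to 3.85) with 5 of 5 members above, chemokines at 3.54-fold and interferon response at 1.97-fold with 8 of 8, and Dlk1 at 147 CPM, Eln at 339 and Serping1 at 249. Cycling cells formed P7 sub-cluster 6 (32 cells, cell cycle genes 14.4-fold) and P30 sub-cluster 6 (26 cells, 42.2-fold).

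**Figure D3:**
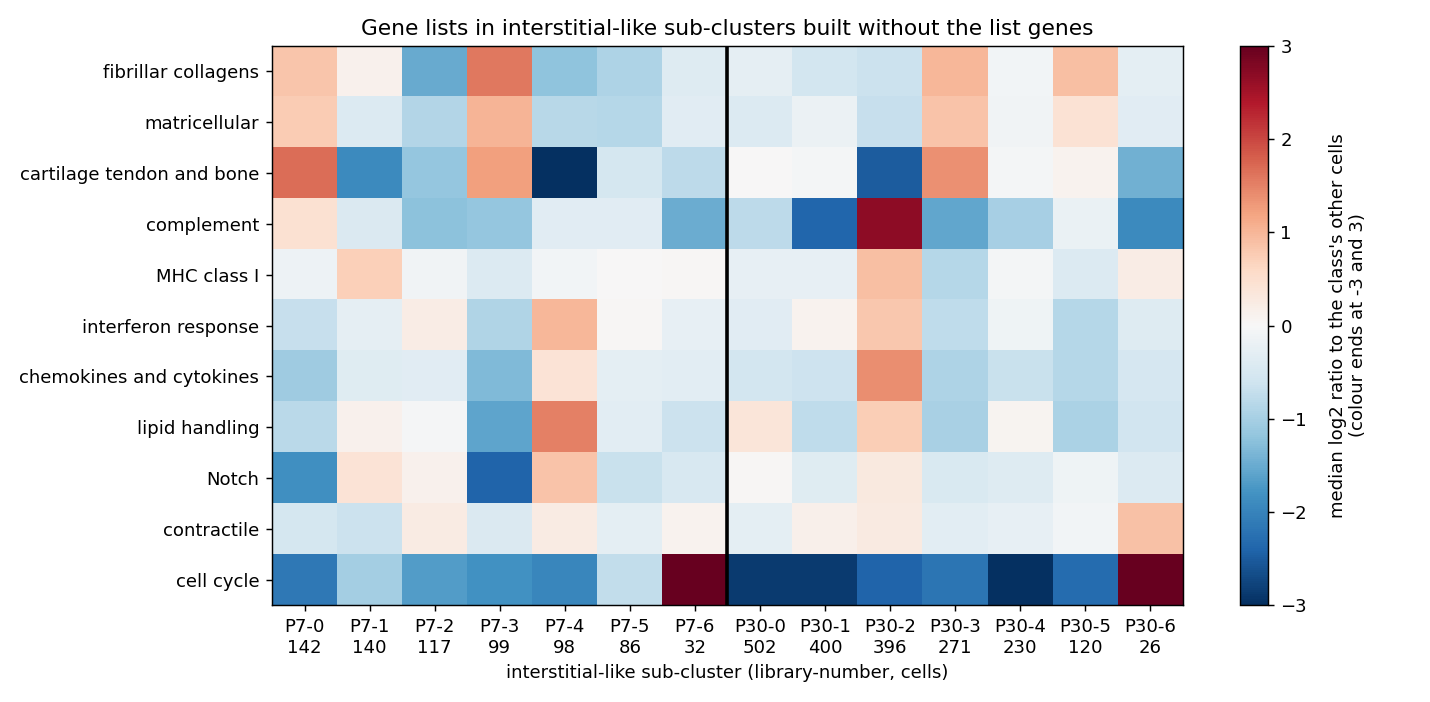
Level of selected gene lists in the interstitial-like sub-clusters of the P7 and P30 libraries. Colour gives the median over list members of the log2 ratio to the other interstitial-like cells of that library, cut at both ends. By summed CPM, which is not drawn, cell cycle genes were 14.4-fold in P7 sub-cluster 6 and 42.2-fold in P30 sub-cluster 6. Cartilage, tendon and bone genes were 2.48-fold in P7 sub-cluster 0 by the same measure, a sum weighted mostly by Mgp.

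Endothelial-like cells differed between the ages in interferon response genes, which were higher in the P30 library. Imprinted growth genes and collagens other than fibrillar were lower, while 13 of 14 genes of valve endothelium were not called higher or lower. Ifi27l2a was at 32.4 CPM (19.5 to 50.7) in the P7 library and 825 (785.5 to 866) in the P30 library, and Cytl1, which encodes a small secreted protein, at 39.3 (24.9 to 58.9) and 403 (375 to 432). H19, an imprinted noncoding RNA of fetal growth, was at 4711 CPM (4537 to 4890) and 867 (827 to 909), and its neighbour Igf2 at 2982 (2843 to 3125) and 956 (913 to 999.8). The basement membrane gene Col4a1 was at 753 CPM (684 to 827) and 225 (205 to 247). These cells were of clusters 4 and 7 in both libraries, 123 P7 cells with 585607 UMIs and 293 P30 cells with 1969333. Barcodes over 20000 UMIs held 28.2% of this class's UMIs at P7 (6 barcodes) and 49.5% at P30 (18 barcodes). Interstitial marker genes were at 1724 CPM in those P7 barcodes and 3076 in the other P7 cells of the class, and at 2632 and 5020.4 in the P30 library.

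Interferon response genes had 16 of 23 members at least 2-fold higher in the P30 endothelial-like cells and 2 lower (median 1.47, 0.80 to 2.09), with Isg15 at 4.35 (2.47 to 7.41), Usp18 at 3.61 (1.05 to 8.95) and Xaf1 at 2.09 higher and Ifitm1 at −1.71 and Rsad2 at −1.50 lower. MHC class I genes had 7 of 15 members higher (median 0.94, 0.46 to 1.86), among them H2-K1 (135 CPM against 636) and B2m (663 against 2844). Immediate early and heat shock genes had 7 of 21 higher and none lower, including Egr1 at 1.33, Fos at 1.2, Dusp1 at 1.28 and Jund at 1.48. The transforming growth factor beta and BMP list had Inhba (353 CPM against 929), Gdf10 and Id1 higher and Tgfb1 and Bmpr2 lower of 18 (median 0.58, 0.04 to 0.91). In the same class mt-Rnr2 was higher at 3.0 and Malat1 at 1.89.

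Imprinted growth genes had 10 of 15 members at least 2-fold lower in the P30 endothelial-like cells and none higher (median −1.39, −2.28 to −0.62), with Mest at −2.84 and Asb4 at −2.52. Collagens other than fibrillar had 6 of 9 lower (median −1.44, −2.30 to −0.47), with Col15a1 at −5.25 (−7.60 to −3.58), Col4a2 at −2.30 and Col18a1 at −1.51. Fibrillar collagens had Col3a1, Col5a1 and Col5a2 lower of 5, elastic fibre genes had 5 of 15 lower, including Eln (135 CPM against 16.8), and 2 higher, Ltbp4 at 1.38 and Efemp1 at 2.02 (0.37 to 4.36, with 3 P7 counts), and matricellular genes had 4 of 9 lower, including Sparc and Postn, and 1 higher, Ctgf at 1.54. Proteoglycan genes had Prg4, Dcn, Prelp and Gpc6 higher and Gpc1 and Vcan lower of 13. Dcn was at 2963 CPM in P30 endothelial-like cells and 18377 in interstitial-like cells of that library, and Mgp at 1138 and 18692. Collagen processing genes had 2 of 15 lower (median −0.36, reversed to 0.21 by thinning to 500 UMIs), and matrix protease and inhibitor genes had Timp3 higher and Adamts4 lower (median −0.14, of the other sign under median-of-ratios scaling).

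Cell cycle genes had 17 of 25 members at least 2-fold lower in the P30 endothelial-like cells and none higher (median −1.22, −1.48 to −0.75), with Mki67 at 256 CPM (217 to 301) against 116 (102 to 132), Ccna2 at −2.30 and Cdk1 at −1.48. Thinned to 500 UMIs, 18.8% (12.2 to 26.7) of P7 and 10.7% (7.30 to 14.7) of P30 cells held at least 2 cell cycle UMIs, intervals that overlap, and without thinning 61.0% and 48.5%. At least 2 UMIs of mitotic genes were held by 16.3% and 14.7% without thinning. The list median was −1.63 without the barcodes over 20000 UMIs, −0.35 with at least 800 genes required per cell, and −0.33 with each library clustered alone. Dll4 at −3.13 and Notch4 at −1.25, a Notch ligand and receptor of vessels, were lower, and the other 6 of 8 Notch genes were not called.

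Genes of valve endothelium had 1 of 14 members called higher or lower between the libraries (median 0.06, −0.69 to 0.65). Wnt9b was at 357 CPM (310 to 409) in the P7 library and 368 (342 to 396) in the P30 library, Pthlh, which encodes parathyroid hormone-related protein, at 633 (571 to 701) and 671 (636 to 709), and Prox1, a transcription factor of lymphatic endothelium, at 283 (242 to 330) and 323 (299 to 350). Hapln1, which encodes a link protein of hyaluronan, was at 567 (508 to 631) and 788 (749 to 828). The member called was Cx3cl1, with 1 UMI in the P7 library (log2 ratio 3.74, 1.19 to 9.08). The flow-responsive Klf4 was at 0.91 and Wnt4 at −0.85. Thinned to 500 UMIs, 16.9% (10.9 to 24.9) of P7 and 14.7% (10.8 to 19.3) of P30 cells had a Prox1 UMI, without thinning 44.7% and 41.6%, and in interstitial-like cells 0.322% and 0.316%. For Wnt9b these were 11.2% (6.36 to 18.4) and 11.7% (8.17 to 15.8), without thinning 29.3% and 34.1%, and in interstitial-like cells 0.103% and 0.0967%. The thinned share was higher in the P30 library for Klf4, at 31.9% (23.6 to 40.7) and 58.0% (52.1 to 63.7), without thinning 61.8% and 87.7%, and in interstitial-like cells 13.1% and 40.3%. For Klf2 the thinned shares were 25.6% (18.5 to 34.7) and 40.2% (34.6 to 46.1). Prox1 lies on chromosome 1 from 190118035 to 190170714, Wnt9b on chromosome 11 from 103727364 to 103749821 and Pthlh on chromosome 6 from 147252101 to 147264183 (mm10, GENCODE M21).

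Several capillary genes rested on 1 barcode. Gpihbp1, Cd36, Fabp4, Meox2 and Rgcc were lower in the P30 library and Aqp1 and Lpl higher of 10 (median −0.96), but 1 P7 barcode held 315 of the 378 Fabp4 UMIs and all 19 of Gpihbp1. Without barcodes over 20000 UMIs Fabp4 was at 45.2 CPM (27.2 to 70.6) in the P7 and 244 (215 to 277) in the P30 library, and the list median was 1.30. Haemoglobin genes had a median of −2.53, with 1442 of the 2181 Hbb-bs UMIs of P7 in 1 barcode, and −0.01 without the deep barcodes. Vascular adhesion genes had Sele and Mcam lower of 13 (median 0.02), and lymphatic genes had Lyve1 and Ccl21a higher of 8 (median 0.19). Wnt genes (median 0.13), lipid handling (0.24), contractile genes (−0.24), chemokines (0.05) and valve mesenchyme transcription factors (−0.22) had at most 2 members called each way.

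Beside Ifi27l2a, Cytl1, Isg15, B2m, H2-K1 and Malat1, the rule named as highest in the P30 endothelial-like cells Snord13 (no count against 85.3 CPM, at least 4.06 on the log2 scale), Vaultrc5 (at least 2.16), the interferon-inducible Ifi27l2b at 3.78 (2.21 to 6.08, with 3 P7 UMIs), the choline kinase gene Chka at 3.37, Ly6a and the chemokine gene Ccl21a. Chka was at 1.73 as the mean over cells, and with each cell thinned to 500 UMIs at 0.92 (−1.35 to 4.17), an interval that spans 0. Ifi27l2b and Snord13 then had no P7 count and were at least 0.62 and 1.25 higher, and Vaultrc5 had 1 P30 count and no ratio. Ly6a was at 195 CPM against 988, and at 207 against 525 without barcodes over 20000 UMIs. Ccl21a had no P7 count and 76.7 CPM in the P30 library, with 145 of its 151 UMIs in 1 barcode, and it has near-identical copies, so which copy was read is uncertain. Highest in the P7 library were 10 Hist1h2a histone genes, from −4.61 for Hist1h2ac to −5.98 for Hist1h2ak, with the same uncertainty of copy, H19_1 (142 CPM against 3.05) and Btnl9. Hist1h2ac and Hist1h2ak were at −2.68 and −3.57 with each library clustered alone, −2.72 and −3.60 with at least 800 genes per cell, and −5.84 and −6.82 without the deep barcodes. The mean over cells put them at −3.95 and −8.03. With each cell thinned to 500 UMIs Hist1h2ac was at −2.99. Hist1h2ak and Hist1h2ae then had no P30 count, at bounds of −2.84 and −1.25, and the interval of Hist1h2ae reached 0.02. H19_1 was at −5.54, at −4.32 as the mean over cells and at −3.25 (−5.72 to −1.36) with each cell thinned to 500 UMIs. Of the 48 Btnl9 UMIs at P7, 47 were in 1 barcode, and with the class rebuilt without the deep barcodes its log2 ratio was −0.23.

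Endothelial-like sub-clusters, again split without listed genes, shared some high listed genes between the libraries, but their likeness was not tested. Prox1 was highest in P7 sub-cluster 2 (35 cells, 1145 CPM) and P30 sub-cluster 0 (88 cells, 1091 CPM), where lymphatic genes were at 3.83-fold (3.13 to 4.67) and 4.0-fold (3.64 to 4.39) the level of the other cells, with 5 of 5 and 8 of 8 members above, and Cldn11 was at 305 and 231 CPM. P7 sub-cluster 1 (35 cells) had Wnt9b at 899.8 CPM, Pthlh at 1523, Hapln1 at 1116 and Dkk2 at 895, and Wnt genes at 3.51-fold (3.07 to 4.02). P30 sub-clusters 1 (62 cells) and 4 (30 cells) had Pthlh at 1014 and 1443 CPM, Wnt9b at 665 and 657, and Wnt genes at 1.54-fold (1.35 to 1.76) and 1.96-fold (1.83 to 2.10). P30 sub-cluster 2 (52 cells) had Fabp4 at 944 CPM, Edn1 at 1003 and Cytl1 at 1397. Cycling cells lay in P7 sub-cluster 0 (53 cells, cell cycle genes 3.55-fold, 25 of 25 members above) and P30 sub-cluster 5 (18 cells, 2.99-fold, 15 of 15), whose cells had a median of 13805.5 UMIs.

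**Figure D4:**
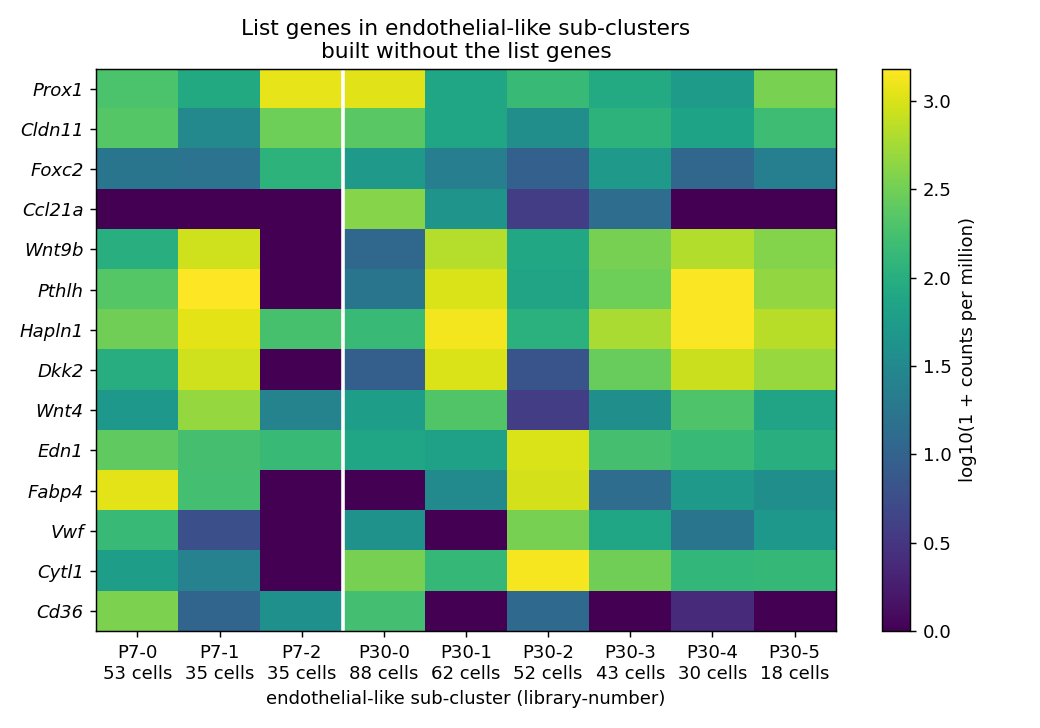
Levels of single listed genes, among them Prox1, Cldn11, Wnt9b, Pthlh and Fabp4, in the endothelial-like sub-clusters of the P7 and P30 libraries, as CPM on a log10 scale. Summed lymphatic genes, which are not drawn as a list, were 3.83-fold in P7 sub-cluster 2 and 4.0-fold in P30 sub-cluster 0.

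Macrophage-like cells of the P30 library stood apart by MHC class II genes, which present antigen to helper T cells. H2-Eb1 was at 120 CPM (66.9 to 197) in the P7 library and 2991 (2860 to 3126) in the P30 library, H2-Ab1 at 183 (116 to 275) and 3234 (3099 to 3374), H2-Aa at 159 (97.4 to 246) and 2437 (2320 to 2559), and the invariant chain gene Cd74 at 534 (414 to 678) and 4022 (3871 to 4178). Of 7 MHC class II genes 6 were at least 2-fold higher (median 3.93, 0.12 to 4.64), and the protease gene Ctss was at 0.12. Thinned to 500 UMIs, 5.51% (1.23 to 16.2) of P7 and 43.7% (37.4 to 50.3) of P30 cells had an H2-Aa UMI, without thinning 11.8% and 55.8%, and in interstitial-like cells 0.509% and 0.640%. Median depths were 2165 and 2338 UMIs. The class was made of clusters 6 and 13, 51 P7 cells with 125478 UMIs and 240 P30 cells with 661355. H2-Eb1 lies on chromosome 17 from 34305867 to 34316674 (mm10, GENCODE M21).

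Chemokine and cytokine genes had 8 of 16 members higher in the P30 macrophage-like cells and none lower (median 0.97, 0.35 to 1.60). Ccl8 had no P7 count and 358 CPM (314 to 407) in the P30 library, at least 3.91 on the log2 scale, and Ccl6 was at 4.50 (1.99 to 9.81), Cxcl1 at 2.29, Tnf at 1.51 and Il1b at 1.21. Genes of resident macrophages had Lyve1 (23.9 CPM, 4.93 to 69.9, against 141, 114 to 172), Folr2, Cbr2 and Cd163 higher of 9, while Mrc1 was at −0.93 and Pf4 at −0.64. Of 4 genes of monocyte-derived macrophages Ms4a4c was higher at 2.38 (0.46 to 5.46), with Lyz2 at 0.96 and Ccr2 at 0.55. MHC class I genes had 9 of 15 members higher (median 1.09, 0.89 to 1.82) and interferon response genes 10 of 24 (median 0.98, 0.26 to 2.25), with Rsad2 at 4.57 (2.06 to 9.88) and Ifitm3 at 3.07. In this class mt-Rnr2 was higher at 3.78.

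Cell cycle genes had 8 of 22 members higher in the P30 macrophage-like cells and none lower (median 1.33, 0.36 to 1.95), with Top2a at 112 CPM (61.0 to 187) against 505 (452 to 562), Mki67 at 1.87, Cenpe at 3.96 (2.08 to 7.02) and Cenpf at 4.17 (1.66 to 9.49). Random lists matched on expression had a median of 0.32 in this class, and this list lay at percentile 100 of them. Without the clusters led by cell cycle genes the list median was 0.28. That setting removed 2 P7 and 35 P30 cells picked by genes of this list, so a lower median was built in. Thinned to 500 UMIs, 24.2% (12.8 to 37.5) of P7 and 30.1% (24.3 to 36.2) of P30 cells held at least 2 cell cycle UMIs, which was not a detectable difference at this depth, and without thinning 72.5% and 68.3%. Lipid handling genes had Plin2 lower at −1.56 of 6, and immediate early genes had Jund higher and Jun and Hspa1a lower of 20 (median 0.04, of the other sign under median-of-ratios scaling).

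Matrix genes were also read at higher levels in the P30 macrophage-like cells, where Dcn was at 63.8 CPM (27.5 to 126) against 1521 (1429 to 1618) and Mgp at 5.06 on the log2 scale. Proteoglycan genes had 7 of 9 members higher (median 1.72) and fibrillar collagens 3 of 4 (median 1.72), at percentiles 100 and 99.7 of the random lists. Elastic fibre genes had 2 of 9 higher (median 0.66, percentile 64.4) and did not stand out from random lists. Complement genes, which are not matrix genes, had 2 of 7 higher (median 0.78, percentile 69.3) and did not either. Over 32 abundant interstitial genes, the level in macrophage-like cells was 1.38% of that in interstitial-like cells at P7 and 7.74% at P30.

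Beside H2-Eb1, H2-Ab1, H2-Aa, Cd74, Ifi27l2a, Malat1 and Ccl8, the rule named Pmp22 in the P30 library (no P7 count against 213 CPM, 180 to 251, at least 3.16). Highest in the P7 library were the iron exporter gene Slc40a1 (175 CPM, 110 to 266, against 7.56, 2.46 to 17.6), Gclm of glutathione synthesis (924, 764 to 1109, against 186, 155 to 222), Tifab at −2.91, the platelet chemokine gene Ppbp at −3.03, Rasl2-9 at −4.40 (−6.86 to −2.51), the skeletal actin gene Acta1 at −2.98, and Mir692-1 and Mir692-2a, which are near-identical copies and uncertain. With each cell thinned to 500 UMIs Acta1 was at −0.91 (−3.52 to 2.48) and Tifab at −1.65 (−3.73 to 0.62), intervals that span 0, and Ppbp had 1 P7 and no P30 count. Gclm, Acta1, Rasl2-9 and both Mir692 genes were also lower at P30 in the other classes compared. Gclm was at −1.73 and Acta1 at −3.33 in endothelial-like cells, and at −1.82 and −3.05 in interstitial-like cells. Slc40a1, Tifab and Ppbp were not measured in those classes. With 125478 UMIs, a P7 macrophage-like gene without a count could lie at up to 23.9 CPM, the floor of 3 counts.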

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

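The tests of explanations in this part, except the one on matrix transcripts in macrophage-like cells, were chosen only after the results were seen, and clustering each library alone was an alternative fixed beforehand.

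Cell cycle genes drew attention because they stood apart in opposite directions in the classes. Their median log2 ratio of P30 over P7 was 1.33 in macrophage-like cells, −1.22 in endothelial-like cells and −1.1 in interstitial-like cells. The size of the gap rested on the setting. In endothelial-like cells the median was −0.33 with each library clustered alone and −0.35 with at least 800 genes per cell. In macrophage-like cells it was 0.28 without the cell cycle clusters. Those clusters were picked by genes of this list, so that lower median was built in. Among macrophage-like cells thinned to 500 UMIs, 24.2% (12.8 to 37.5) at P7 and 30.1% (24.3 to 36.2) at P30 held at least 2 cell cycle UMIs, intervals that overlap. The difference between the classes was not tested, since each age has 1 library. Top2a was 2.18 higher on the log2 scale in the P30 macrophage-like cells, and −0.56 and −0.30 in the endothelial-like and interstitial-like cells.

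Thymocyte genes drew attention because cluster 9, which enters no comparison, held 137 UMIs of Rag1, Dntt, Cd8a, Cd8b1 and Ccr9 in the P7 library, far above the limit that a count of 0 allows. The P30 library held 58 in that cluster. Rag1 and Dntt encode enzymes that build antigen receptor genes in developing lymphocytes. They held 19 and 18 of the P7 UMIs and 6 and 8 of the P30 UMIs, and Cd8a, Cd8b1 and Ccr9 held the others. At P7 12.2% of the library's UMIs of all the thymocyte genes lay outside the cluster, where 97.1% of all UMIs lay, which argues against free RNA. Cells with at least 2 such UMIs numbered 21 at P7 (2.2%, 1.36 to 3.34) and 13 at P30 (0.372%, 0.198 to 0.635). Thymus tissue carried along at dissection and thymocytes or other T cells in the valve or blood cannot be told apart, as no thymus or blood was sampled.

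Interferon response and MHC class I genes were higher in the P30 library in all 3 classes compared. A first test of free RNA asked whether the CPM added at P30 differed over 2-fold between classes, and gave 2.13 (1.91 to 2.36), which left it open. A second, chosen after that, set the added CPM against the 820.0 that free RNA could add, and found at least 6.1 times as much. The added CPM was 4988 in interstitial-like, 6028 in endothelial-like and 10628 in macrophage-like cells. The 820.0 took free RNA at 9.49%, the highest interstitial marker level in endothelial-like or macrophage-like cells relative to interstitial-like cells. That share was applied to the P30 library's own level of these genes, 8644 CPM, when the rises were already known. The outcome was thus largely set in advance, and RNA of cells that were not captured is not covered. No conclusion on free RNA is drawn from this test. Erythroid-like cells were not counted in the 9.49%. They had Dcn at 10446 CPM, against 18377 in P30 interstitial-like cells, so a higher share stays open. Leaving out barcodes over 20000 UMIs, which held 28.2% and 49.5% of endothelial-like and 0% of macrophage-like UMIs, left the lower of the 2 endothelial-like medians at 0.9905, which argues against a few deep barcodes. The sequencing run and the age cannot be told apart, since each age had 1 library and the libraries carried different run names. The ribosomal RNA mt-Rnr2, with no immune function, was also higher by at least 2.54 in every class compared, which does not separate them. A biological difference of age remains open and untested.

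Matrix transcripts were higher in P30 macrophage-like cells. Over 32 interstitial genes, the log2 ratios of P30 over P7 in macrophage-like and interstitial-like cells had a Spearman's rho of 0.79 across genes, which are not independent replicates. This is consistent with free RNA of interstitial cells, whose level in macrophage-like cells was 1.38% of the interstitial level at P7 and 7.74% at P30. Multiplets of macrophages with interstitial cells were not tested apart from it, and an age difference in the macrophages themselves stays open.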

How the results depend on the processing

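The settings of at least 800 genes, without deep barcodes, cluster 1 counted as interstitial and without cell cycle clusters were chosen after seeing the data. With 1 library per age no result has a replicate check, and depth limits the P7 macrophage-like class (51 cells) most. Over 13 alternative settings, 1843 values of 165 results were recomputed, of which 1675 stayed within the interval of the reported value, 167 moved beyond it and 1 reversed. Reversed means that a log2 value whose interval excluded 0 took the other sign. Of 1040 values of shares and lists, 998 stayed, 41 moved and 1 reversed. For lists the interval is the spread over members, so staying within it is a weak check. The mean over cells and the authors' normalized table are the same calculation, and both were counted. Of 1750 log2 values 68 took the other sign, and apart from the reversed one the interval of the reported median spanned 0, so 66 count as stayed and 1 as moved. All 773 values of the 64 ratios named by the rule (50 genes, some in more than 1 class) kept their sign, and 765 were still at least 2-fold. After thinning, 26 of these 64 had no count in 1 library and gave only a bound against a floor of 3 counts, or no ratio. The named genes were chosen as the most extreme in these data. Those with no count in their lower library could not change sign, so the kept signs are no support. A minimum of 500 genes removed no barcode and the authors' barcodes were the same set, so neither was run. For every value below, the cause was not tested.

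The share of interstitial-like cells at P30 was 50.4% at Leiden resolution 1.5, 59.4% with doublets kept, 52.4% with each library clustered alone and 80.7% with cluster 1 counted as interstitial. With each library clustered alone, the share of macrophage-like cells at P7 was 0%, and median log2 ratios were −0.33 for endothelial cell cycle, −1.53 for interstitial cell cycle and −3.20 for interstitial haemoglobin genes. With cluster 1 counted, interstitial cell cycle was −1.38.

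With at least 800 genes per cell, 7.65% of P7 and 2.36% of P30 interstitial-like cells held 2 cell cycle UMIs, and medians were −0.35 for endothelial cell cycle, −1.68 for interstitial cell cycle and −3.23 for interstitial haemoglobin. The mean over cells and the authors' normalized table, which gave the same medians within 5.33e-15, had interstitial cell cycle at −1.41, interstitial haemoglobin at −2.45 and endothelial haemoglobin at −1.82.

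Median-of-ratios scaling gave 0.22 for endothelial vascular adhesion and, in interstitial-like cells, 0.39 for transforming growth factor beta and BMP, 0.72 for immediate early and 2.26 for cartilage, tendon and bone genes. With no expression minimum macrophage vascular adhesion was 0.60.

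Thinning to 500 UMIs per cell reversed endothelial collagen processing, from −0.36 to 0.21. It also gave interstitial complement 1.89, cell cycle −1.72 and haemoglobin −2.39, endothelial elastic fibre −1.20, Notch 0.99 and haemoglobin −1.75, and macrophage nuclear oxidative phosphorylation 0.31, immediate early 0.31, vascular adhesion 0.57 and transforming growth factor beta and BMP 1.17.

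Without barcodes over 20000 UMIs, endothelial haemoglobin was −0.0064, cell cycle −1.63, and capillary genes went from −0.96 to 1.30. Without cell cycle clusters, interstitial cell cycle was −1.43, macrophage cell cycle 0.28 and macrophage valve mesenchyme transcription factors 2.32.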

Other observations

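Melanocyte-like cells, pigment cells known to populate mouse valves, carried pigment genes in both libraries. In 14 P7 and 16 P30 cells the melanin enzyme gene Dct was at 44130 CPM (42173 to 46153) and 51444 (48888 to 54098), the melanosome gene Pmel at 7917 (7101 to 8800) and 3524 (2880 to 4270), Mlana at 4062 and 3457, and the tyrosinase gene Tyr at 1292 and 474. Mitf, their master transcription factor, was at 1062 and 576, the endothelin receptor gene Ednrb at 5262 and 3050, and Ptgds at 369 and 1389. Dendritic-like cells, 6 at P7 and 57 at P30, held H2-Aa at 4328 and 6419 CPM and H2-Ab1 at 7748 and 11872. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 534 CPM (419 to 672) at P30, in 10 of 57 cells, and Xcr1, a gene of cross-presenting dendritic cells, at 373 in 22 cells, while 6 P7 cells are too few to compare either gene.

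When cluster 1 was joined to the P30 interstitial-like cells (2818 cells) and these were split without listed genes, a small interferon-rich group stood out, which was looked at after the clusters were seen. Its 51 cells, 29 of cluster 1, were led by Cxcl9, Iigp1, Gbp8, Gbp4 and Igtp, and held interferon response genes at 4.11-fold (3.93 to 4.29) the level of the others with 19 of 20 members above, MHC class I genes at 3.41-fold (3.27 to 3.56) and MHC class II genes at 5.54-fold (4.79 to 6.38). Gbp2 was at 886 CPM, Ifit1 at 600 and Cxcl10 at 589. Sub-clusters 3 (352 cells, 251 of cluster 1) and 6 (244 cells, 168 of cluster 1) held MHC class II genes at 3.67-fold (3.32 to 4.04) and 4.59-fold (4.17 to 5.04), and sub-cluster 1 (444 cells, 304 of cluster 1) held contractile genes at 1.60-fold (1.54 to 1.66). Without the 22 interstitial-like cells of the interferon-rich group, the class medians were 1.90 for interferon response, 2.17 for MHC class I and 2.37 for complement, against 1.98, 2.2 and 2.36 with them.

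Cluster 9 held further immune cells in small numbers. Cells with at least 2 T and NK cell marker UMIs numbered 26 at P7 and 23 at P30, and cells with at least 2 mast cell marker UMIs 6 and 7. The cytotoxic gene Gzmb had 0 UMIs at P7 and 35 at P30, and the chemokine gene Ccl5 0 and 129.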
